A study of Osmanthus fragrans with 6 samples.

How the data were processed

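Petals of Osmanthus fragrans var. semperflorens were sampled at 4 stages of flowering round 1 and 2 stages of round 2. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was selected with poly-T beads, and libraries were sequenced on an Illumina instrument. Per the series' design text, 5 replicates were pooled into 1 library for each stage. The reads were assembled de novo, per the series title, which means that transcripts were rebuilt from the reads without a genome. CASAVA 1.7 is named in the submitters' processing notes. The assembler, aligner and counting tool are not given in the sources used here, nor is how reads shared by near-identical transcripts were divided, so a transcript's level can include reads of a close copy.

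The authors deposited a table of estimated counts for 96596 transcripts in 6 columns, 1 per library, with no scaling between libraries. The unit was read from the values, which were unscaled and whole except for 36 to 855 decimal values in a column. Each transcript came from a different assembly gene. Every column name matched the labels of 1 sample, and the number of columns without a sample was 0. Expected counts were rounded to whole numbers before use.

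Depth ran from 107466 counts in initial 1 to 39119103 in initial 2. Transcripts with at least 1 CPM in at least 1 of the 6 libraries were kept, which left 30524 (31.6%) and at least 99.2% of the counts of each library. Libraries were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3. The factors were 1.51 for initial 1, 1.06 for full 1, 0.912 for late full 1, 0.711 for abscission 1, 1.11 for initial 2 and 0.869 for full 2. With every library thinned to the depth of initial 1, the factor of initial 1 was 1.13 and that of full 1 was 1.10, so the value of 1.51 rests in part on depth. Levels are CPM divided by these factors, called scaled CPM. Log2 ratios used a prior count of 2.

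With 1 library per group no spread within a group was measured, so no test between groups was made and no p-value is given. A model adding stage and round over the 6 libraries, in which their interaction would stand in for the error, was not fitted. A transcript was counted as differing when its ratio was at least 4-fold and the pair held at least 50 counts. The 7 planned comparisons were full against initial in each round, late full against full, abscission against late full and abscission against initial in round 1, and round 2 against round 1 at the initial and full stages. Folds of named transcripts have exact 95% Clopper-Pearson intervals on the pair of counts, divided by the scaled library sizes. A fold against a count of 0 was taken against a floor of 3 counts in that library and is given as at least that fold. Such a bound is not the lower limit of the exact interval. For c159830_g1_i1 at abscission against initial 1 the floor gave 467-fold and that limit was 380. Intervals and floors cover counting error only, since reads are not independent molecules and pooled plants add a spread that was not measured.

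Counting error was simulated by drawing 20 sets of Poisson counts for each pair from the pair's shared levels at the real library sizes, and counting the calls. Agreement between repeated comparisons was given as Pearson and Spearman correlations of log2 ratios across transcripts, with the overlap that independent lists of the same sizes would have. The course of round 1 was described for transcripts with at least 50 counts over its 4 libraries and a range of at least 4-fold. Libraries were compared by correlation and by principal components of log2 CPM. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 did the remaining steps.

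The named transcripts follow a rule written at the same time as the comparisons. For abscission against initial, full against initial, and round 2 against round 1, it takes the 2 highest and 2 lowest transcripts that differ at least 4-fold with at least 200 counts in the higher library. Where a comparison was made in 2 pairs, the ratio was at least 2-fold the same way in both, at least 4-fold with 200 counts in at least 1 of them, and transcripts were ranked by the smaller ratio. The ratios of this rule include the prior count, so a count of 0 in initial 1 can pass it without a detectable difference. Lists fixed in advance, for carotenoid biosynthesis and cleavage, the MEP pathway, scent terpenes, flavonoids, photosynthesis, senescence, abscission, hormones, floral identity, pollen, cell cycle, ribosomal proteins and stress, could not be applied to IDs without gene names and give no result here.

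Settings listed before the data were examined were DESeq2 1.42.0 size factors, total counts only, no filter, fold thresholds of 2 and 8, minimums of 10 and 200 counts, a prior count of 0.5, and thinning to the shallowest library. Chosen after seeing the data were a lower count raised to 3, a subset of 1952 transcripts with a mean of 100 CPM or more, that subset with total counts only, initial 1 left out of the filter and scaling, and the 5 deeper libraries thinned to the shallowest of them. The calling step was tested on simulated counts with 200 planted transcripts. All planted 8-fold and 16-fold differences were recovered (100%) for late full 1 against full 1 over 23059 transcripts and for full 2 against initial 2 over 25441, and 0% of unchanged transcripts were called. For full 1 against initial 1, over 17958 transcripts, 77% of 8-fold and 88% of 16-fold differences were recovered, and 19.6% of unchanged transcripts were called.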

Results

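Petal messenger RNA of Osmanthus fragrans var. semperflorens, a sweet osmanthus that flowers in repeated rounds, was measured by RNA sequencing across flowering. The series addresses flower colour and the genes of carotenoid biosynthesis over the flowering stages. Petals came from trees grown outdoors and were collected in September. Round 1 of flowering gave 4 libraries, at the initial, full, late full and abscission stages (initial 1, full 1, late full 1 and abscission 1). Round 2 gave 2 libraries, at the initial and full stages (initial 2 and full 2). Each library pooled 5 replicates before sequencing, so every group is 1 library with no replicate error, and no difference between stages or rounds has a replicate check. Ratios are therefore given without p-values, and the intervals given cover counting error only.

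The 6 libraries held counts for 96596 assembled transcripts. Initial 1 held 107466 counts, full 1 held 19797488, late full 1 held 25917466, abscission 1 held 17826689, initial 2 held 39119103 and full 2 held 19240153. Initial 1 thus had 0.603% of the depth of the next shallowest library, and 1 count there stood for 9.31 CPM (counts scaled to a common library total). It had counts for 15286 transcripts, against 56799 to 69732 in the other 5 libraries. The table pairs transcript IDs with no gene names, so the transcripts are named by ID and the carotenoid genes were not analysed here.

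The comparison of abscission with the initial stage covers the whole course of round 1. Transcript c159830_g1_i1 stood at 8616 scaled CPM at abscission, with 109251 counts, and had 0 counts in initial 1. It was at least 467-fold higher at abscission with TMM scaling, taking 3 counts as the floor of initial 1, which is 18.4 scaled CPM. Its level was 30.3 scaled CPM in full 1 and 1464 in late full 1, so most of the difference lay after the full stage. Transcript c155541_g1_i1 was at least 317-fold higher at abscission, with 6.03 scaled CPM in full 1, 1012 in late full 1 and 5843 in abscission 1. With total counts in place of TMM scaling, these bounds were 220-fold for c159830_g1_i1 and 149-fold for c155541_g1_i1. Transcript c151095_g1_i1 was 7.02-fold lower at abscission than in initial 1 (95% interval 6.10 to 8.03). It stood at 1408, 1002, 517 and 201 scaled CPM over the 4 stages. Transcript c134566_g1_i1 was 6.08-fold lower (95% interval 5.53 to 6.67) and went from 2970 scaled CPM in initial 1 through 2063 and 919 to 489. The intervals leave out the scaling, and with total counts c151095_g1_i1 was 14.9-fold and c134566_g1_i1 12.9-fold lower. All 4 transcripts moved the same way from initial 2 to full 2. There c159830_g1_i1 went from 29.2 to 241 scaled CPM, c155541_g1_i1 from 12.2 to 494, c151095_g1_i1 from 1048 to 471 and c134566_g1_i1 from 2295 to 926.

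**Figure D1:**
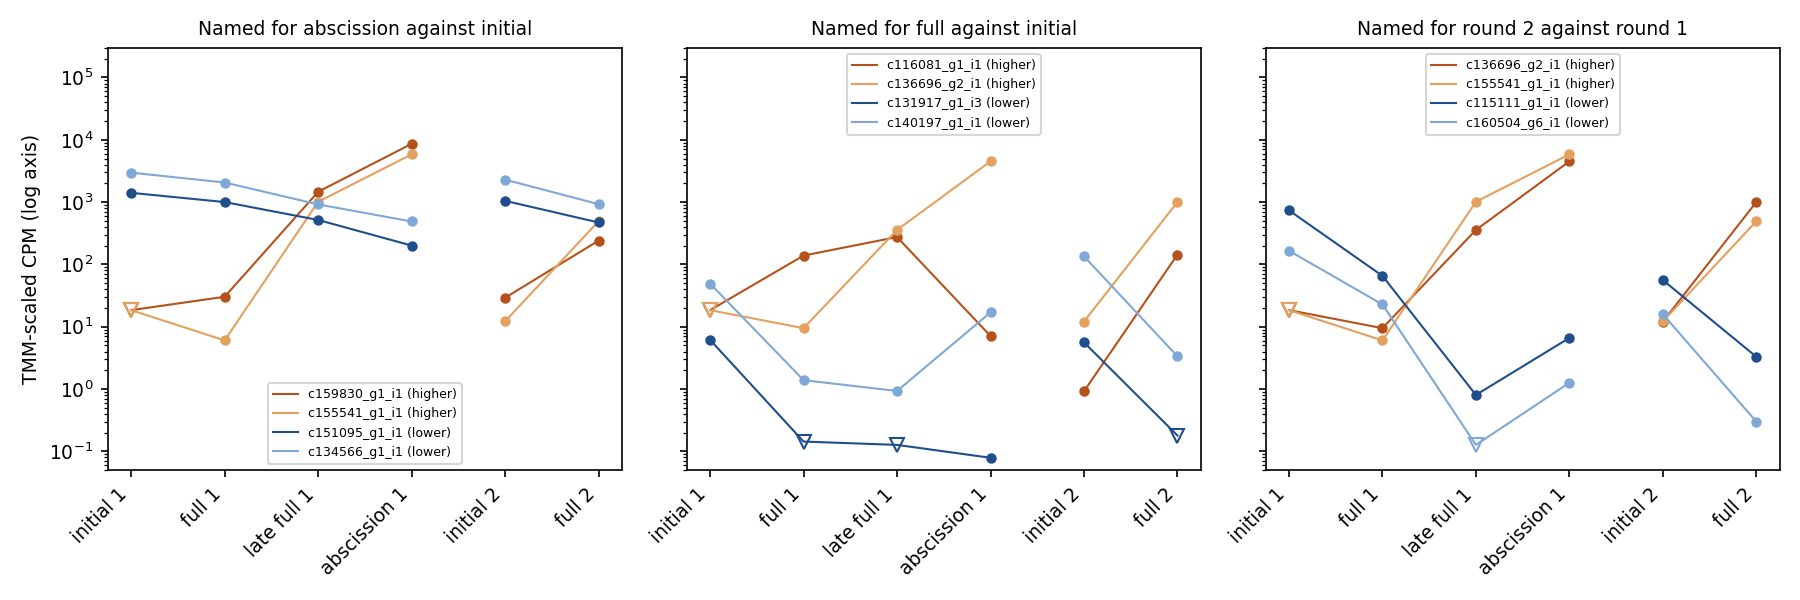
Level of each transcript named by the selection rule in the 6 libraries, as TMM-scaled CPM on a log axis, with lines joining the stages of a round. Filled circles are measured levels and open triangles mark a count of 0, drawn at the level of 3 counts in that library, so a line that starts or ends at a triangle shows no direction of its own. c159830_g1_i1 reached 8616 and c155541_g1_i1 reached 5843 scaled CPM in abscission 1.

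Between abscission 1 and initial 1, 5835 of 15867 transcripts with enough counts differed at least 4-fold, 5416 higher and 419 lower at abscission. Of the higher transcripts, 4031 had 0 counts in initial 1, and counting error at that depth alone gave 2120 calls. Among the 1952 transcripts with a mean of 100 CPM or more, a subset chosen after the data were seen, 444 differed at least 4-fold, against 2.45 from counting error alone. Of these, 390 were higher and 54 lower at abscission. The split depends on the scaling: total counts gave 4510 higher and 1872 lower over all transcripts, and 199 higher and 191 lower in the abundant subset. The median log2 ratio of the abundant subset was 0.58 with TMM and -0.51 with total counts. The direction of a typical transcript between these libraries was therefore not determined.

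The steps between neighbouring deep libraries of round 1 were smaller, and counting error alone gave 0 calls in both. At these depths the 4-fold threshold and the minimum of 50 counts nearly fix that outcome. It does not bear on the spread between pools, which was not measured. From full 1 to late full 1, 1255 of 23059 transcripts differed at least 4-fold, 804 higher and 451 lower in late full 1. Total-count scaling gave 673 higher and 618 lower, with a median log2 ratio of -0.21. From late full 1 to abscission 1, 2073 of 21753 transcripts differed, 1109 higher and 964 lower at abscission. Total counts turned this balance, with 778 higher and 1390 lower and a median of -0.27. In the abundant subset, 81 transcripts were higher and 14 lower in late full 1 than in full 1. In the same subset, 69 were higher and 19 lower in abscission 1 than in late full 1, or 46 and 37 with total counts. Abscission 1 against full 1, a pair added after the data were seen, gave 3249 differing transcripts, 1909 higher and 1340 lower. With total counts these were 1328 and 2482, and the median log2 ratio was -0.53.

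Over the 4 stages of round 1, 15534 of 25050 transcripts had a range of at least 4-fold. The level was highest in abscission 1 for 5952 of them, in late full 1 for 3762, in full 1 for 3612 and in initial 1 for 2208, but 12506 were lowest in the shallow initial 1. With total counts the order turned, with 5140 of 16582 transcripts highest in full 1, 4219 in initial 1, 3717 in abscission 1 and 3506 in late full 1. Without initial 1, 5164 transcripts had such a range, with 2240 highest in abscission 1, 1640 in full 1 and 1284 in late full 1. Of these 5164, 1862 were higher at each successive stage and 1351 lower at each. In the abundant subset, 554 transcripts had a 4-fold range over the 4 stages, and 338 (61.0%) were highest in abscission 1. With total counts this share was 34.2% of 524 transcripts, and 137 were higher at each stage while 137 were lower at each.

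Full against initial bloom was the stage difference measured in both rounds, in pairs that share no library. Transcript c116081_g1_i1 was 156-fold higher in full 2 than in initial 2 (95% interval 115 to 219), at 144 against 0.921 scaled CPM. In round 1 it stood at 139 scaled CPM in full 1 against 0 counts in initial 1, at least 7.51-fold higher or 5.24-fold with total counts, then at 275 in late full 1 and 7.10 in abscission 1. Transcript c136696_g2_i1 was 83.2-fold higher in full 2 than in initial 2 (95% interval 76.3 to 91.0). The interval leaves out the scaling, and with total counts c136696_g2_i1 was 65.2-fold higher. In round 1 it had 198 counts in full 1 and 0 in initial 1, a difference not detectable at that depth. It reached 4510 scaled CPM in abscission 1. Transcript c140197_g1_i1 was lower at full bloom in both rounds, 35.4-fold in round 1 (95% interval 14.0 to 79.4, on 8 counts in initial 1) and 40.2-fold in round 2 (95% interval 30.9 to 53.3). Transcript c131917_g1_i3 had 243 counts in initial 2 and 0 in full 2, at least 31.2-fold lower at full bloom. In round 1 it had 1 count in initial 1 and 0 in full 1, both under the floor of 3 counts, so no fold is given. Among the deep libraries it lay almost wholly in initial 2, with 0 counts in late full 1 and 1 in abscission 1. The cause of such confinement stays open.

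In round 2, 3870 of 25441 transcripts differed at least 4-fold between full and initial bloom, 1888 higher and 1982 lower in full 2. Total counts gave 1449 higher and 2801 lower, with a median log2 ratio of -0.41. Thinning the 5 deep libraries to equal depth gave 1743 higher and 1144 lower. In round 1, 5882 of 17958 differed, 5538 higher and 344 lower in full 1, and 4882 of the higher ones had 0 counts in initial 1. With a lower count raised to 3, a setting chosen after the data were seen, the balance turned to 235 higher and 344 lower. This setting acts on 1 side, since 3 counts are 18.4 scaled CPM in initial 1 but 0.144 in full 1. It left the 344 lower calls as they were, so the turned balance gives no direction. Counting error alone gave 3750 calls in this pair and 0.1 in round 2. In the abundant subset, 172 transcripts were higher and 16 lower in full 2 than in initial 2, around a median log2 ratio of 0.36. In the same subset, 163 were higher and 7 lower in full 1 than in initial 1, around a median of 0.67. With total counts these medians were 0.01 in round 2, with 134 higher and 28 lower, and 0.16 in round 1, with 97 higher and 13 lower.

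Across 17896 transcripts, the log2 ratios of full to initial bloom in the 2 rounds had a Pearson r of 0.17 and a Spearman rho of 0.23, where transcripts are not independent replicates. Of the transcripts differing at least 4-fold in round 1, many of which may be counting error, 57.0% moved the same way in round 2, against 59.5% of all transcripts. Of those differing at least 4-fold in round 2, 68.0% moved the same way in round 1. At least 4-fold higher at full bloom in both rounds were 602 transcripts, against 299 for independent lists. At least 4-fold lower in both were 87, against 17.0. With total counts the shares were 47.9% of the round 1 calls, 64.6% of the round 2 calls and 58.7% of all transcripts. Among 1951 abundant transcripts, r was 0.58 and rho 0.54, and 94.7% of the round 1 differences had the same direction in round 2, against 72.1% of all transcripts of the subset. In that subset 82 transcripts were at least 4-fold higher at full bloom in both rounds, where independent lists would share 14.3. A further 5 were at least 4-fold lower in both, against 0.06 for independent lists.

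Round 2 was compared with round 1 at the initial stage and at full bloom. Transcript c136696_g2_i1 was 106-fold higher in full 2 than in full 1 (95% interval 92.3 to 123), at 1006 against 9.48 scaled CPM. Transcript c155541_g1_i1 was 81.9-fold higher in full 2 than in full 1 (95% interval 68.7 to 98.5), at 494 scaled CPM in full 2. The intervals leave out the scaling, and with total counts c136696_g2_i1 was 87.5-fold and c155541_g1_i1 67.5-fold higher. Within round 1, c136696_g2_i1 reached 357 scaled CPM in late full 1 and 4510 in abscission 1, and c155541_g1_i1 reached 1012 and 5843. High levels of these transcripts were thus not particular to round 2. Round cannot be told apart here from a later point within the full stage. Neither c136696_g2_i1 nor c155541_g1_i1 had a count in initial 1. Their levels in initial 2, 12.1 and 12.2 scaled CPM, were under the floor of initial 1, so no difference was detectable at the initial stage. Transcript c115111_g1_i1 was lower in round 2 at both stages, 13.2-fold at the initial stage (95% interval 10.9 to 15.8) and 19.9-fold at full bloom (95% interval 15.2 to 26.6). It stood at 738 scaled CPM in initial 1 and 56.0 in initial 2, and at 0.804 in late full 1. Transcript c160504_g6_i1 was 10.5-fold lower in initial 2 than in initial 1 (95% interval 6.86 to 15.4) and 76.2-fold lower in full 2 than in full 1 (95% interval 32.4 to 236, on 5 counts in full 2). Within round 1 this transcript had 0 counts in late full 1 and 1.26 scaled CPM in abscission 1. For c115111_g1_i1 the level was 6.62 in abscission 1 and 3.29 in full 2. Low levels of both were thus not particular to round 2.

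At full bloom, 2239 of 21652 transcripts differed at least 4-fold between the rounds, 1370 higher and 869 lower in round 2. Total counts gave 1117 higher and 1175 lower, with a median log2 ratio of -0.21. The abundant subset had 98 higher and 6 lower in full 2, around a median of 0.20, or 74 and 12 around a median of -0.08 with total counts. At the initial stage, 10051 of 22940 transcripts differed, 9393 higher and 658 lower in initial 2. Of the higher ones, 8895 had 0 counts in initial 1, and counting error alone gave 7868 calls, 7245 of them higher. With a lower count raised to 3 the balance turned to 152 higher and 658 lower. This setting acts on 1 side, since 3 counts are 18.4 scaled CPM in initial 1 but 0.0691 in initial 2. It left the 658 lower calls as they were, so the turned balance gives no direction. In the abundant subset 117 were higher and 7 lower in initial 2, against 8.3 calls from counting error alone. With total counts the subset had 75 higher and 13 lower, and its median log2 ratio went from 0.50 to 0.05. Over all transcripts, total counts gave 9110 higher and 1286 lower. The log2 ratios of round 2 to round 1 at the 2 stages had r of 0.13 and rho of 0.15 across 20241 transcripts, and r of 0.49 and rho of 0.39 across 1950 abundant ones. In the abundant subset, 48 transcripts were at least 4-fold higher in round 2 at both stages, where independent lists would share 5.76.

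**Figure D2:**
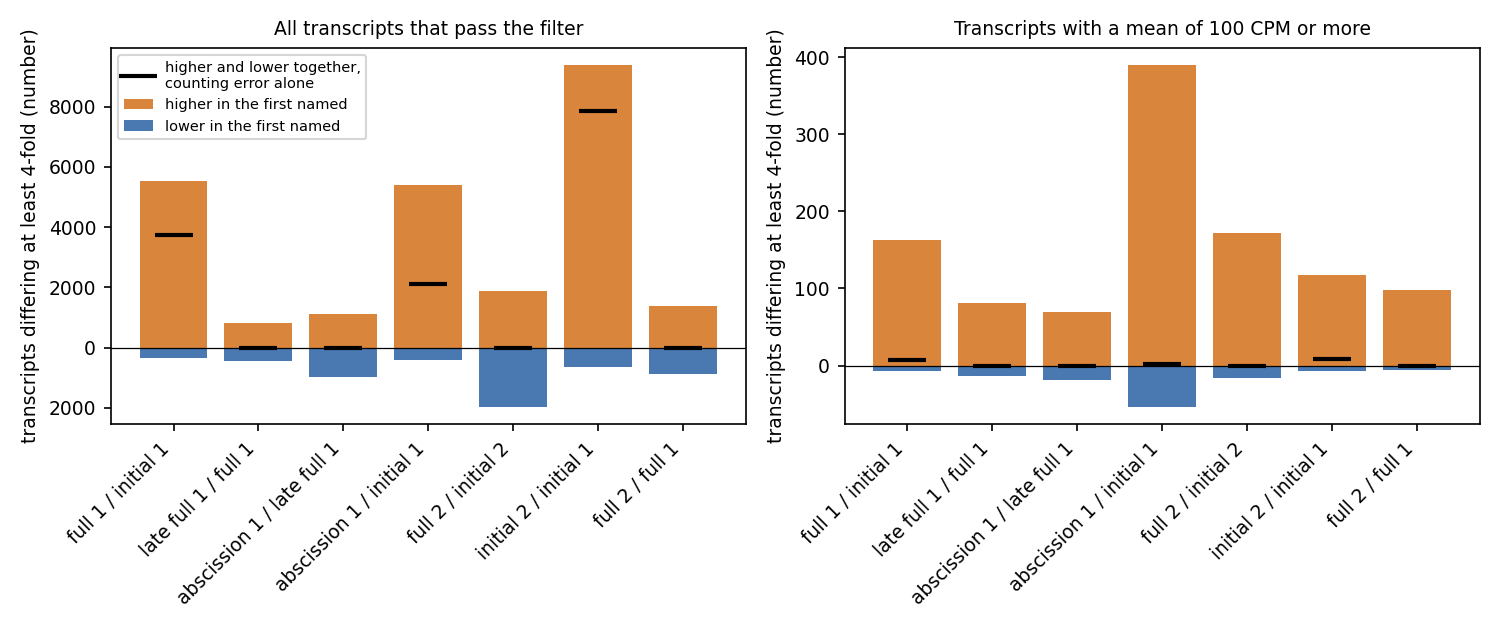
Number of transcripts at least 4-fold higher (orange, above 0) and lower (blue, below 0) in the library named before the slash, for the 7 planned comparisons with TMM scaling. The left panel has all transcripts that passed the filter and the right panel the 1952 with a mean of 100 CPM or more. Black bars mark the mean number of calls from counting error alone over 20 simulations without change, which was 7868 for initial 2 against initial 1, where 10051 were observed.

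Between libraries, log2 CPM correlated across the 30524 kept transcripts at r of 0.946 for full 1 and initial 2, 0.926 for full 1 and late full 1, and 0.911 for abscission 1 and full 2. Full 2 correlated with late full 1 at 0.866 and with full 1 at 0.867. Among the 1952 abundant transcripts, full 2 lay nearer to late full 1 (r of 0.818) and abscission 1 (0.716) than to full 1 (0.680). With every library thinned to the depth of initial 1, r over the transcripts then kept was 0.833 with late full 1, 0.827 with full 1 and 0.809 with abscission 1. In the abundant subset 41 transcripts differed at least 4-fold between full 2 and late full 1, and 104 between full 2 and full 1, while over all kept transcripts these counts were 2321 of 22417 and 2239 of 21652. In the abundant subset initial 1 lay nearest to initial 2 (r of 0.757) and full 1 (0.728), and its r with abscission 1 was -0.01 (rho 0.12). Over all kept transcripts these r were 0.732, 0.721 and 0.625. The abundant subset was picked on the mean CPM of these same libraries, which narrows the range and can by itself lower r. The size of r in the subset is therefore not comparable with that over all kept transcripts. In a principal component analysis without initial 1, component 1 held 50.8% of the variance. Full 1 (-0.64) and initial 2 (-0.66) lay at its negative end, late full 1 at -0.17, and full 2 (0.63) and abscission 1 (0.83) at the positive end. Component 2 held 24.9% and set full 2 (-0.62) apart from late full 1 (0.62) and abscission 1 (0.34).

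**Figure D3:**
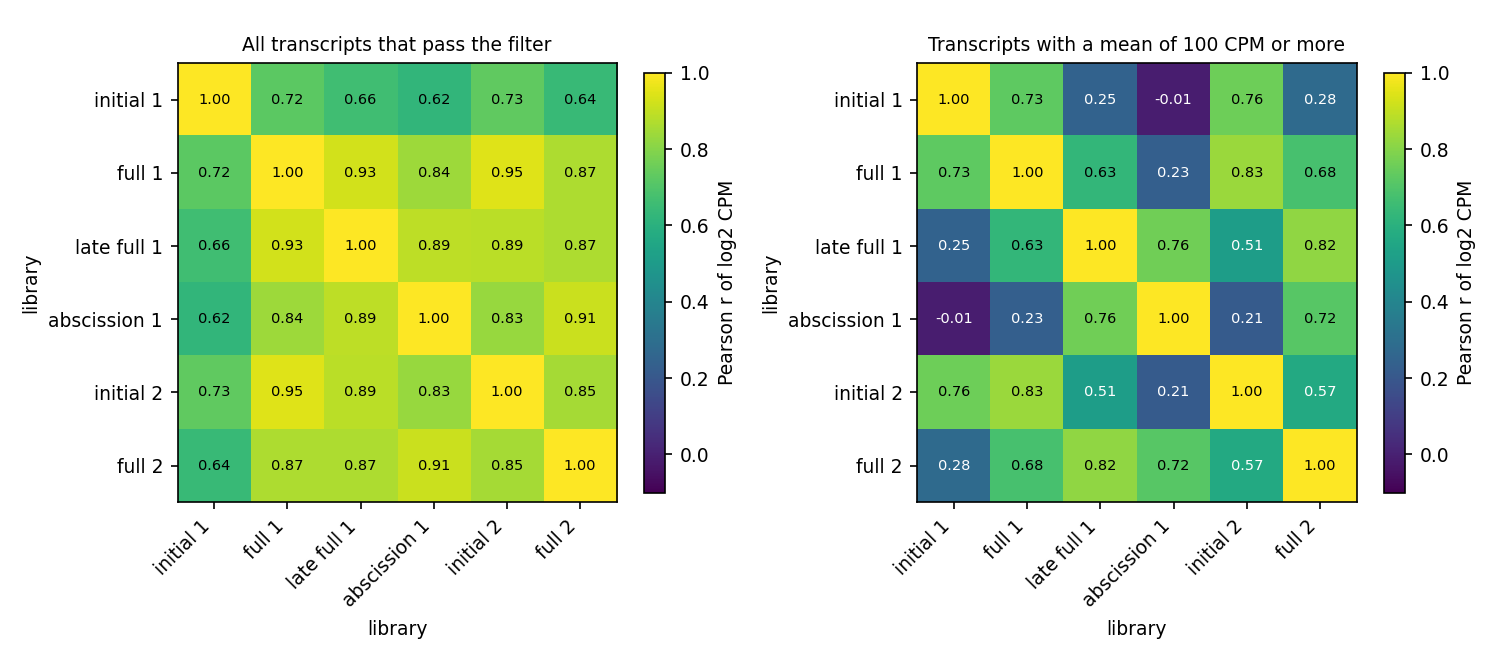
Pearson r of log2 CPM for each pair of libraries, printed in each square and coloured on a linear scale, across all transcripts that passed the filter (left) and across those with a mean of 100 CPM or more (right). In the right panel full 2 has r of 0.818 with late full 1 and 0.680 with full 1. Its transcripts were picked on the mean of these same libraries, which can lower r.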

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

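The tests of the initial-stage libraries in this part were stated before their results were seen, while the subset of abundant transcripts they use in part was chosen after seeing the data. Between the rounds, 360 transcripts were at least 4-fold higher at full bloom than at the initial stage in 1 round and at least 4-fold lower in the other. This count rests in part on full 1 against initial 1, where simulated counting error without any change gave 3750 calls and the data gave 5882. Independent lists would give 289 such transcripts, and 354 of the 360 were higher in round 1 and lower in round 2. Between the stages, 439 transcripts were at least 4-fold higher in round 2 than in round 1 at 1 stage and at least 4-fold lower at the other, against 306 for independent lists. Of these, 422 were higher in round 2 at the initial stage and lower in round 2 at full bloom. Calls in the same direction exceeded independent lists as well. Between the rounds 602 transcripts were higher in both, against 299, and 87 lower in both, against 17.0. Between the stages 609 were higher in both, against 287, and 43 lower in both, against 17.0. The opposite moves therefore do not show that the rounds or the stages oppose each other. Neither excess of opposite moves over independent lists holds at a 2-fold threshold, with 1276 transcripts against 1556 for the rounds and 1514 against 1526 for the stages. Both held at an 8-fold threshold, with 113 against 72.1 and 148 against 87.4. They also held with a minimum of 10 counts (1417 against 1152 and 1342 against 990) and with total counts (495 against 403 and 574 against 404). With a minimum of 200 counts the rounds gave 46 against 50.2 and the stages 66 against 52.8. With 1 library per group, neither difference was tested. Both counts of opposite moves were 0 among the transcripts with a mean of 100 CPM or more. Independent lists would give only 1.95 and 0.70 there, so the subset does not bear on these counts.

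Initial 2 against initial 1, which enters the count of opposite moves between the stages, gave 10051 transcripts with at least 4-fold differences. Counting error at the depth of initial 1 alone gave 78.3% of that number, so many of these calls may be counting error. Among transcripts with a mean of 100 CPM or more it gave 6.69% of the 124 differing, which argues against counting error for the abundant ones. That initial 1 is a random part of the initial 2 library is excluded by the correlation across 1952 transcripts. It was 0.775 between initial 1 and a thinned initial 2, which is 0.14 below the 0.915 between a pair of thinned copies of initial 2. A difference between rounds, and a difference in RNA or library making that goes with the low depth of initial 1, stay open and cannot be separated with 1 library each.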

How the results depend on the processing

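The settings named as added in the methods were chosen after seeing the data. Of 141 alternative values of the 11 main results, 77 stayed within 1.5 times the main count or 0.1 of the main r, 60 moved further and 4 changed sign. DESeq2 size factors, no filter and a prior count of 0.5 moved none of the 11. The cause of the changes was not tested beyond what each setting fixes by its construction. In the order full 1 against initial 1, late full 1 against full 1, abscission 1 against late full 1, abscission 1 against initial 1, full 2 against initial 2, initial 2 against initial 1 and full 2 against full 1, a minimum of 200 counts gave 1947, 648, 896, 2705, 1875, 3440 and 943 differing transcripts. Thinning to the shallowest library gave 23, 40, 58, 188, 64, 15 and 38. A mean of 100 CPM or more gave 170, 95, 88, 444, 188, 124 and 104, and with total counts 110, 91, 83, 390, 162, 88 and 86. A 2-fold threshold gave 9550, 4684, 6314, 9248, 9931 and 6381 in that order without initial 2 against initial 1. A minimum of 10 counts gave 14244, 1990, 3765, 13262, 15334 and 4411 without full 2 against initial 2. An 8-fold threshold gave 470 for late full 1 against full 1, 737 for abscission 1 against late full 1, 1477 for full 2 against initial 2 and 934 for full 2 against full 1. Raising a lower count to 3 gave 579 for full 1 against initial 1, 1435 for abscission 1 against initial 1 and 810 for initial 2 against initial 1, and thinning the 5 deeper libraries gave 5708 for the last pair. The r of full to initial bloom between rounds went from 0.17 to 0.278 with 200 counts, 0.585 when thinned to the shallowest library, 0.580 in the abundant subset and 0.576 there with total counts. The r of round 2 to round 1 between stages went from 0.13 to 0.389, 0.492 and 0.493 under the last 3 of these. Transcripts with a 4-fold range in round 1 numbered 7247 with 200 counts, 418 thinned, 554 in the abundant subset, 524 there with total counts, and 5164 with initial 1 left out. The r of full 2 with late full 1 minus that with full 1 was -0.000677 and changed sign to 0.00199 with total counts, 0.00539 thinned, 0.138 (0.137606) in the abundant subset and 0.138 (0.137639) there with total counts. Of 307 alternative values of secondary counts and of the Spearman correlations, 158 stayed within those limits and 149 moved. The settings listed for the gene lists were not run, since the IDs carry no gene names. No analysis paired by round was run. Depth limits every comparison with initial 1, where a level under 18.4 scaled CPM cannot be told from 0 counts.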

Other observations

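In this part the tests of full 2 against the round 1 stages and of the transcripts nearly confined to 1 library or to round 2 were chosen or revised after the results were seen. Counts were more concentrated late in round 1. The 10 most abundant transcripts took 17.3% of the counts in abscission 1 and 11.5% in late full 1, against 5.87% to 6.79% in the other 4 libraries. The 10 leading transcripts of abscission 1 took 10.8% of the counts in late full 1, 5.34% in full 2, 3.25% in initial 2, 3.23% in initial 1 and 2.45% in full 1. Abscission 1 shared 8 of its 10 leading transcripts with late full 1, 6 with full 2 and 1 with full 1, while full 1 shared 8 with initial 2.

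A small number of transcripts lay almost wholly in 1 of the 5 deep libraries, with at least 50 counts and 95% of their scaled CPM over those libraries there. Full 2 had 80, with 21615 counts or 0.112% of that library, late full 1 had 24, initial 2 had 12, abscission 1 had 10 and full 1 had 0. The 24 of late full 1 held 2300 counts and had 0 in every other library. Over the rounds, 124 transcripts had at least 50 counts in round 2 and at most 3 in round 1, with 20272 counts in full 2 and 2495 in initial 2. The reverse held for 48 transcripts.

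Full 2 lay toward abscission 1 compared with full 1. Of 2135 transcripts at least 4-fold higher in abscission 1 than in initial 2, 92.0% were higher in full 2 than in full 1, and of 2136 at least 4-fold lower, 83.9% were lower, with a gap of 2.62 between the median log2 ratios. The gap was 2.48 at equal depth, but full 1 and full 2 already held similar counts, 19797488 and 19240153. Thinning could therefore hardly move it and decides little. Among transcripts with a mean of 100 CPM or more the gap was 2.13, which argues against low counts as the cause, mainly for the rising ones. There the median was 1.51 for 229 rising transcripts and -0.62 for 78 falling ones, of which 71.8% were lower in full 2. A mixture of the full 1 and abscission 1 profiles stays open: the share of abscission 1 it needs had a median of 28.8% over 202 transcripts, was below 0 for 0 of them and above 100% for 20, and its upper quartile was 3.101 times the lower (95% bootstrap interval 2.52 to 3.97), a spread that differences between pools, not measured here, could also give. The gap was 2.73 with total counts, which decides nothing because a library factor moves both sets alike. The flowering round, a later sampling point within the full stage and a wrong label all stay open as untested. Late full 1 lay the same way, with a gap over full 1 of 1.97, or 2.39 among the abundant transcripts. For full 2 over late full 1 the gap was 0.38, 0.009 at equal depth and -0.50 among the abundant ones. By this gap full 2 was thus not clearly beyond late full 1. Component 1 without initial 1 did place it beyond, at 0.63 against -0.17 for late full 1 and 0.83 for abscission 1. Over all kept transcripts r with abscission 1 was 0.911 for full 2 and 0.891 for late full 1. Among the abundant ones these r were 0.716 and 0.760. Whether full 2 lay beyond late full 1 therefore depended on the measure.

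The cause of the transcripts nearly confined to 1 library or to round 2 stays open. Simulated counting error gave 0 such transcripts, both over the 5 deep libraries and in round 2, but the minimum of 50 counts fixes that outcome, so the comparison decides nothing. A candidate source of the 124 round 2 transcripts is RNA from outside the petals. Such a source of fixed composition would give each transcript the same share of counts from initial 2, which was 10.96% over all of them, and the shares differed with a chi-square of 111 per degree of freedom over 123 degrees. This covers counting error only, so it does not exclude that source, and a changing source, sequence differences between trees and expression set by the round were not tested.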
